A study of Mus musculus with 27 samples.

How the data were processed

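Messenger RNA bound to tagged ribosomes was measured in the striatum of male mice aged 2 to 5 months on a mixed strain background. Per the labels' protocols, translating ribosome affinity purification (TRAP) was used: a GFP-tagged ribosomal protein is expressed in 1 neuron type, its ribosomes are immunoprecipitated with a mix of 2 anti-GFP antibodies, and the RNA that comes with them is amplified by the two-cycle Affymetrix kit. Mice carried the tag in neurons that express the dopamine receptor D1 or D2, and both floxed copies of G9a (Ehmt2), a histone H3 lysine 9 methyltransferase. Mutants also carried Cre under the promoter of the same receptor, and controls carried no Cre, so genotype also stands for the Cre transgene. Per the series' design text, mice were taken 2 h after the last of 8 injections, at 20 mg/kg/day in the cocaine groups, with 2 to 4 mice per group. The mice are therefore the replicates, and p-values measure the spread between these samples.

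The deposited table holds log2 values of 45101 probe sets on 27 Affymetrix whole-genome mouse arrays, which the authors made by robust multi-array averaging (RMA) in Affymetrix Expression Console 1.1, per the submitters' processing notes. The design text names another Affymetrix program with global scaling for the scans. The values themselves (array medians from 5.70 to 5.82, maxima from 14.23 to 14.46) have the log2 scale and the even distributions of RMA. The number of arrays limits the precision.

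Of the probe sets, 64 were controls, 34945 had exactly 1 gene symbol in the 2016 array annotation, 932 had several and 9160 had none. Each of 18193 gene symbols was represented by its probe set with the highest mean over all arrays, and genes were tested when that probe set exceeded 6 on the log2 scale in at least 3 arrays, which left 12017 genes. No 2 arrays held the same values: the smallest mean absolute difference between a pair was 0.137 log2.

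All arrays were fitted together in limma 3.58.1 on R 4.3.3, with 1 mean for each of the 8 groups of subtype, genotype and drug. The contrasts were D1 against D2 neurons in controls, mutant against control in each subtype with the drugs weighted equally, the difference of these effects (D2 minus D1), cocaine against saline in each subtype and genotype, and the difference of the cocaine effect between genotypes in each subtype. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 are said to have risen or fallen. The replicate numbers in the titles were not treated as pairs.

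Gene lists were tested with limma's camera, which compares a list with the other genes at a preset inter-gene correlation of 0.01, when at least 5 members were tested. Camera with an estimated correlation and fry were run beside it. The lists were markers of D1 and D2 medium spiny neurons (MSN), of all MSN, of cholinergic and GABAergic interneurons, cortical excitatory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, blood, and ependyma and choroid plexus. The others were immediate early genes, the H3K9 methylation machinery, germline genes, developmental transcription factors of other tissues, muscle structural genes, imprinted genes, neuropeptides, glutamate receptors, GABA-A receptor subunits, potassium channels, clustered protocadherins, cholesterol synthesis, cytosolic ribosomal proteins, oxidative phosphorylation, and heat shock with the unfolded protein response. For a wider view of subtype identity, the 100 genes most enriched in D1 and in D2 neurons were defined on the control arrays of 1 drug and tested in mutants against controls on the arrays of the other drug, so that no array served both purposes.

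RNA quality was measured per array as the mean 3' minus 5' log2 difference of the Gapdh and Actb control probe sets, and compared by exact permutation tests, 2-sided. The contrasts, tests, filter, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, per contrast, up to 12 passing genes with the largest change in each direction (for G9a loss, those with the same sign under both drugs), the 5 smallest p-values where none passes, the target, the D1 and D2 MSN markers, and up to 4 members of each other list by smallest p. Genes without a proper name were counted but not named. Cocaine contrasts pooled over subtypes and genotypes, a fit without 3 arrays with a high Ttr level (above 9.5 log2), the genes plotted and the cholinergic genes were chosen after the data were seen.

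Alternatives covered the choice of probe set, the filter, cyclic loess and median centring on top of the deposited values, moderation with a trend, array weights, the replicate number as a block, covariates for RNA quality and for glial markers, a fold of at least 1.5, and leaving out each array. One D2 mutant cocaine array (replicate 4) has a source name that calls it a control, so it was also counted as one. In simulated data with 200 of 12017 genes changed, a log2 change of 1 was recovered in 100% of them for G9a loss in each subtype and in 96.6% for cocaine in D1 controls, against 41.9% at a change of 0.5. For the difference of the cocaine effect between genotypes a change of 1 was recovered in 75% in D1 and 90.7% in D2, and a change of 0.5 in 25.6% and 22.9%. With no list changed in simulated data, 0 lists were called by camera. Genes varied independently in that simulation, so it could not show how often camera calls lists of correlated genes. Gene positions came from RefSeq annotation of GRCm38.p6 and served only to find neighbouring genes. Probe sets without a symbol were left out of the gene counts.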

Results

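Ribosome-bound RNA of D1 and D2 neurons, the main projection neuron types of the striatum, was measured on 27 arrays. Of the 13 D1 arrays, 6 came from controls (2 saline, 4 cocaine) and 7 from G9a mutants (3 saline, 4 cocaine). Of the 14 D2 arrays, 7 came from controls (3 saline, 4 cocaine) and 7 from mutants (3 saline, 4 cocaine). Between 61.4% and 63.7% of genes lay above the floor of 6 on the log2 scale per array, and the lowest correlation of an array with another of its group ranged from 0.971 to 0.993. Ttr, an abundant choroid plexus transcript, ranged from 5.40 to 12.36 and was high in 3 arrays: D1 control cocaine replicate 3 (9.67), D1 mutant saline replicate 3 (12.36) and D2 control cocaine replicate 3 (11.40). Changes are log2 fold changes with their standard error (SE) where given.

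The RNA quality measure was compared by genotype and by drug within each subtype, and none of these tests passed. In D1 arrays its mean was 2.30 in mutants (SD 0.174, n = 7) and 2.29 in controls (SD 0.35, n = 6), a difference of 0.018 (exact permutation p = 0.902). In D2 arrays the difference between mutants and controls was 0.024 (exact permutation p = 0.792). Cocaine minus saline was 0.113 in D1 arrays (exact permutation p = 0.483) and -0.08 in D2 arrays (exact permutation p = 0.381). All 4 adjusted values were 0.902. Among D1 controls, however, the cocaine arrays (2.167 to 2.904) lay above both saline arrays (1.956 and 2.012), which was not tested on its own.

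The comparison of D1 with D2 neurons in controls asked which transcripts separate the neuron types in mice without Cre. D1 neurons had higher Drd1, the D1 receptor (6.05-fold, SE 0.116 on the log2 scale, adjusted p = 6.53e-15), the transcription factors Isl1 (3.58, adjusted p = 7.6e-17), Ebf1 (2.87) and Zfp521 (2.61), the opioid peptide precursor Pdyn (3.42) and the substance P precursor Tac1 (1.33). D2 neurons had higher Drd2, the D2 receptor, with a D1 minus D2 difference of -6.50 (SE 0.117, adjusted p = 1.73e-23, 90.2-fold lower in D1). They also had higher Gpr6, an orphan receptor (-5.01), the enkephalin precursor Penk (-2.67), the kainate receptor Grik3 (-3.97) and the ectonucleotidase Nt5e (-3.50). Other genes with large differences were Eya1 (6.49), Slc35d3 (3.60), Tcfl5 (3.44), Crh (3.21), Rasgrf2 (2.72), Sfxn1 (2.71) and Neurod6 (2.43) on the D1 side. On the D2 side they were Ttc12 (-6.69), Upb1 (-2.89), Nell1 (-2.89), Lhx8 (-2.75), Ptprm (-2.42), Oprd1 (-2.25) and Fst (-2.23). Background limits the size of differences for genes under the floor of 6 in 1 subtype, such as Ttc12, Upb1, Lhx8, Oprd1 and Nt5e in D1 and Ebf1, Tcfl5 and Neurod6 in D2 controls. The call of Neurod6 ended without D1 control saline replicate 2 (1.52, adjusted p = 0.132). The target itself, Ehmt2, did not pass (-0.32, adjusted p = 0.0765), and its partner Ehmt1 passed (-0.49, adjusted p = 0.0442) but not without any 1 of 11 arrays, such as D2 control saline replicate 1 (-0.33, adjusted p = 0.156).

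**Figure D1:**
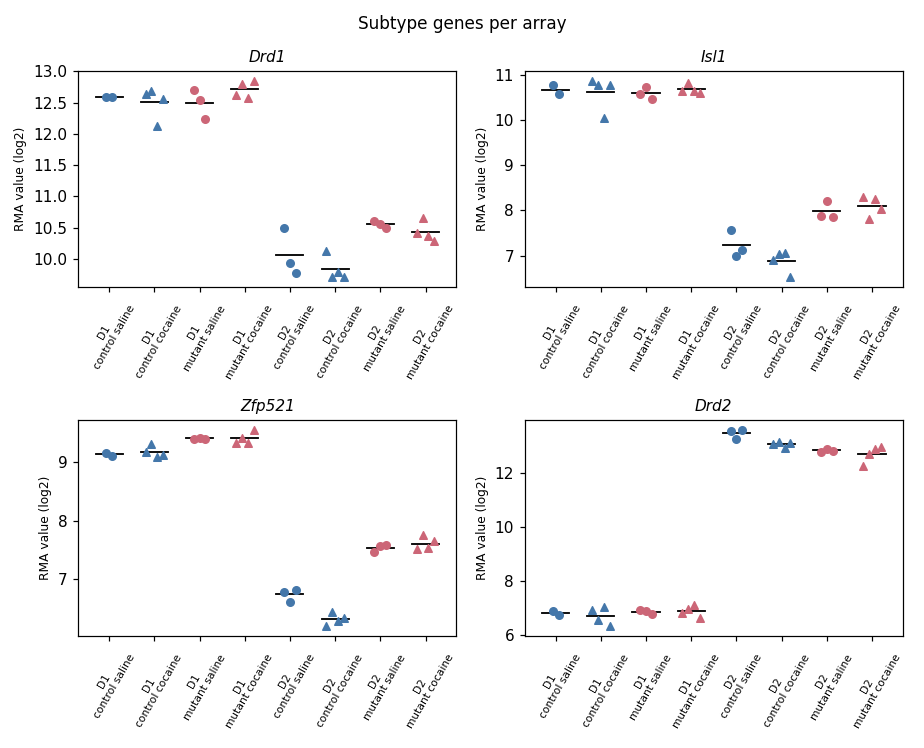
Log2 expression of Drd1, Isl1, Zfp521 and Drd2 on each array by subtype and genotype, with controls in blue, mutants in red, saline as circles, cocaine as triangles and the group mean as a line. Drd1 averaged 10.07 in D2 control saline and 10.55 in D2 mutant saline arrays, against 12.60 in D1 control saline arrays.

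All 9 tested D1 MSN markers were higher in D1 neurons (9 adjusted over the list alone, camera adjusted p = 1.83e-28, and 8.98e-05 with an estimated correlation). Of 11 D2 MSN markers 10 were lower in D1 neurons (10 adjusted over the list alone, camera adjusted p = 4.72e-23, and 8.98e-05 with an estimated correlation), while Cd4 did not pass (0.16, adjusted p = 0.13). Of 21 immediate early genes 9 were higher in D1 neurons and 12 did not pass (10 higher adjusted over the list alone, adjusted p = 0.515 with an estimated correlation), including Fos (1.88) and Nr4a1 (1.73). Of 15 neuropeptides 8 were higher, 3 lower and 4 did not pass (8 and 3 adjusted over the list alone, adjusted p = 0.251 with an estimated correlation). Lower in D1 neurons were 32 of 36 cytosolic ribosomal protein genes, with 1 higher and 3 not passing (32 lower and 1 higher adjusted over the list alone, median -0.42, for example Rpl19 at -0.55), and 46 of 63 oxidative phosphorylation genes, with 17 not passing (51 lower and 1 higher adjusted over the list alone, median -0.26, for example Ndufa7 at -0.55). With an estimated correlation their adjusted p-values were 0.163 and 0.313. Of 12 clustered protocadherins, neuronal adhesion molecules, 4 were lower and 8 did not pass (5 lower adjusted over the list alone, adjusted p = 0.515 with an estimated correlation), among them Pcdhb9 (-1.01). Of 18 pan-MSN markers 2 were higher, 7 lower and 9 did not pass (2 and 7 adjusted over the list alone, adjusted p = 0.0297, and 0.515 with an estimated correlation), with Ptpn5 at -0.52 and Gad2 at 0.55. Under cyclic loess that list's adjusted p was 0.336.

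Markers of other cell types also differed. Of 9 astrocyte markers 2 were higher in D1 neurons (Aldoc 1.05, Gja1 0.60) and 7 did not pass (4 higher adjusted over the list alone, adjusted p = 0.00821, and 0.434 with an estimated correlation). Of 12 oligodendrocyte markers 6 were lower (Mag -0.44, Ugt8a -0.98) and 6 did not pass (7 lower adjusted over the list alone, adjusted p = 0.0635, 0.573 with an estimated correlation and 0.0406 under cyclic loess). Of 5 cortical excitatory markers 3 were higher, Nrn1 at 1.59 first, and 2 did not pass (4 higher adjusted over the list alone, adjusted p = 0.0178, and 0.313 with an estimated correlation). Of 8 GABAergic interneuron markers 4 were higher and 4 did not pass (4 adjusted over the list alone, adjusted p = 0.135), for example Calb2 (0.49). Without D1 control saline replicate 2 the call of Gja1 ended (0.39, adjusted p = 0.204).

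The remaining lists moved both ways or little between subtypes. Imprinted genes included 7 higher, led by Dlk1 (2.05), 7 lower and 10 not passing (7 and 7 adjusted over the list alone). Glutamate receptors had 5 higher, 3 lower and 10 not passing (6 and 3 adjusted over the list alone), including Grik2 (0.69) and Grin2b (0.78). GABA-A subunits had 2 higher (Gabrb1 0.93, Gabrg1 0.73), 2 lower and 5 not passing (3 and 4 adjusted over the list alone). Potassium channels had 8 higher, 4 lower and 21 not passing (8 and 4 adjusted over the list alone), with Kcnc4 at 1.09 and Kcnk2 at -0.89. H3K9 machinery genes had 1 higher (Cdyl 0.31), 2 lower (Setdb2, Ehmt1) and 20 not passing (1 and 1 adjusted over the list alone), with a median of -0.04 and a mean of -0.02 while camera pointed up (adjusted p = 0.707). Cholesterol synthesis had 1 higher, 2 lower and 14 not passing (1 and 2 adjusted over the list alone), and heat shock genes 1 higher, 6 lower and 22 not passing (1 and 6 adjusted over the list alone), with Manf at -0.77. The tested members of the endothelial, muscle and developmental transcription factor lists (6, 11 and 16 genes) did not pass.

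In total 1428 genes were higher in D1 neurons and 2052 were higher in D2 neurons. The higher ones made up 41.0% of the 3480 calls, and 52.6% under cyclic loess. Without D1 control saline replicate 2 the count was 2310.

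The comparison of mutants with controls in D1 neurons asked what the loss of G9a changed there. Ehmt2 fell (-1.79, SE 0.135, adjusted p = 4.49e-10, 3.45-fold lower), and the 7 mutant arrays (8.03 to 9.37) lay below the 6 controls (9.95 to 10.74). These values are of the brighter of 2 probe sets. The other lay near the floor and overlapped between genotypes in D1 (5.38 to 5.82 in mutants, 5.59 to 5.97 in controls) and D2 (5.24 to 5.82 and 5.75 to 6.26), and the labels do not say which exons are floxed. Afp, the fetal serum protein alpha-fetoprotein, rose most (6.76, SE 0.152, adjusted p = 3.89e-21), from 4.08 (SD 0.212, n = 4) in cocaine-treated controls, under the floor of 6, to 10.82 (SD 0.22, n = 4) in cocaine-treated mutants. Dach2, a developmental transcription factor, rose by 6.17 (adjusted p = 4.41e-24) and Corin, a protease of heart muscle, by 3.58. Other large rises were those of Ccdc141 (4.78), the B cell scaffold Bank1 (3.01), Zranb3 (2.72), the glycogen branching enzyme Gbe1 (2.65), Cst12 (2.11), Hacd2 (2.07), Tmprss11a (1.92), Gstm7 (1.91) and the BMP regulator Bmper (1.91). Dach2, Corin, Ccdc141, Cst12 and Tmprss11a also lay under the floor in D1 controls, where background limits the fold. The activin antagonist Fst fell (-1.75, adjusted p = 1.98e-09), as did Reep6 (-1.50), Rps4l (-1.22), Fxyd7 (-1.18), Amn (-1.11), Marcksl1 (-1.04), Il17rc (-0.92), Klc3 (-0.91), Epop (-0.89), Marveld3 (-0.85) and Fbln5 (-0.83). The call of Marcksl1 ended without D1 control saline replicate 2 (-0.75, adjusted p = 0.0611).

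**Figure D2:**
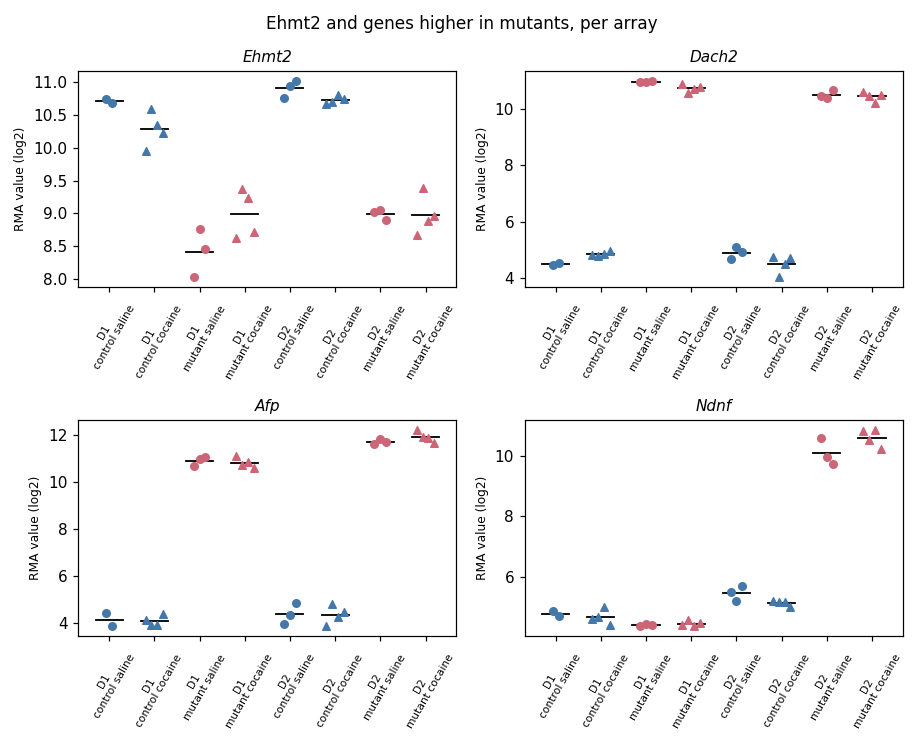
Log2 expression of Ehmt2, Dach2, Afp and Ndnf on each array by subtype and genotype, with controls in blue, mutants in red, saline as circles, cocaine as triangles and the group mean as a line. The main Ehmt2 probe set was lower on every mutant array than on any control array of its subtype, and Ndnf averaged 10.10 in D2 mutant saline arrays against 4.43 in D1 mutant saline arrays.

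Few identity markers of the neurons passed in D1 mutants. Zfp521 was the only 1 of the 9 D1 MSN markers that rose (0.25, adjusted p = 0.0155, and 1 adjusted over the list alone, camera adjusted p = 0.112), and its call ended without D1 control saline replicate 1 (0.26, adjusted p = 0.0676) or 2 (0.24, adjusted p = 0.0872). The D1 MSN list passed without D1 control cocaine replicate 2 (median 0.20, adjusted p = 0.0388), while with all arrays it had 0.93 with an estimated correlation. Drd1 (0.06, adjusted p = 0.911), Pdyn (0.40, adjusted p = 0.215) and the 11 D2 MSN markers, with Drd2 at 0.10 and Penk at -0.23, did not pass. Without D1 mutant saline replicate 3 Pdyn passed (0.53, adjusted p = 0.042), and Penk passed without D1 mutant cocaine replicate 2 (-0.31, adjusted p = 0.0217). Of the 100 D1-enriched genes defined on cocaine arrays, 71 were higher in saline D1 mutants (median 0.27, adjusted p = 0.00425, and 0.995 with an estimated correlation), of which 3 rose and 1 fell. That list's adjusted p was 0.24 without D1 mutant saline replicate 1 (median 0.15), 0.296 without D1 control saline replicate 1 (0.08) and 0.0663 without D1 control cocaine replicate 4 (0.19). Defined on saline and tested on cocaine arrays the D1-enriched median was 0.01 (adjusted p = 0.61), and D2-enriched medians were 0.00 in cocaine (adjusted p = 0.986) and 0.01 in saline arrays (adjusted p = 0.954). With fixed marker lists D1-enriched genes passed in cocaine (0.232, adjusted p = 0.0258) and not in saline arrays (0.059, adjusted p = 0.427), nor did they with 50 genes per list in saline arrays (0.251, adjusted p = 0.139).

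Clustered protocadherins rose together in D1 mutants: 8 of 12 rose and 4 did not pass (12 rose adjusted over the list alone, adjusted p = 1.36e-15, and 0.0339 with an estimated correlation), for example Pcdhb21 (0.83), Pcdhb15 (0.81) and Pcdhb16 (0.80). Of 23 H3K9 machinery genes Ehmt2 fell, Atf7ip rose (0.44) and 21 did not pass (1 and 1 adjusted over the list alone, adjusted p = 0.0177, and 0.773 with an estimated correlation). This list holds the target Ehmt2 itself, whose fall the genotype sets, and it was not tested without that gene. Its call thus does not speak for the other members. Atf7ip did not pass without any 1 of 8 arrays, such as D1 control saline replicate 2 (0.42, adjusted p = 0.158). Of 11 muscle structural genes 2 rose, the troponin Tnnt2 (1.70) and the myosin Myh7 (0.50), and 9 did not pass (3 rose adjusted over the list alone, median -0.03, mean 0.24, camera up, adjusted p = 0.294). Of 16 developmental transcription factors Dach2 rose and 15 did not pass (1 adjusted over the list alone, median -0.06, mean 0.32, camera down, adjusted p = 0.744). Of 24 imprinted genes Plagl1 (0.71) and Ndn (0.47) rose and 22 did not pass.

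Single members passed in other lists in D1 mutants. Th (0.99) rose among 8 GABAergic interneuron markers, Ermn (1.57) among 12 oligodendrocyte markers, Scg2 (0.48) among 15 neuropeptides, Gabrb1 (0.50) among 9 GABA-A subunits and Kcna6 (1.25) among 33 potassium channels. The metabotropic receptor Grm3 (-0.82) fell among 18 glutamate receptors, Tm7sf2 (-0.33) among 17 cholesterol genes and Hspa1a (-0.35) among 29 heat shock genes. Adjusted over the list alone, neuropeptides and GABA-A subunits each had 1 rise and 1 fall, and 1 astrocyte marker rose. The neuropeptide median was 0.03 and the mean -0.01. The calls of Tm7sf2 (-0.27, adjusted p = 0.144) and Hspa1a (-0.31, adjusted p = 0.212) ended without D1 control saline replicate 2, among other arrays for Hspa1a. The pan-MSN, cortical, astrocyte, endothelial, immediate early, ribosomal and oxidative phosphorylation members did not pass over all genes.

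In all, 373 genes rose and 134 fell in D1 mutants (73.6% of 507 calls rose, and 64.1% under median centring). The risen genes had a median control level of 7.06, and 20.4% of them averaged below the floor in controls, against 5.3% of all tested genes. The filter favours such a gap, since genes low in controls are mostly tested through other arrays where they are higher. Without D1 control saline replicate 1 the count was 319.

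The same comparison in D2 neurons asked what G9a loss changed in the other subtype. Ehmt2 fell (-1.82, SE 0.126, adjusted p = 4.7e-11), with 7 mutant arrays from 8.68 to 9.38 and 7 controls from 10.67 to 11.02. Drd1 rose in D2 mutants (0.54, SE 0.108, adjusted p = 0.00113), as did Isl1 (0.98, SE 0.121, adjusted p = 1.71e-06) and Zfp521 (1.04, SE 0.058, adjusted p = 7.65e-13), while Drd2 fell (-0.49, adjusted p = 0.00315). Isl1 averaged 6.88 (SD 0.243, n = 4) in cocaine-treated D2 controls and 8.09 (SD 0.218, n = 4) in mutants, against 10.61 in D1 controls. Lhx8, a transcription factor of cholinergic interneurons, which also express Drd2 and Isl1, rose (1.17, SE 0.155, adjusted p = 5.79e-06), and was named after its values were seen. Its means were 8.20 and 9.13 in saline and 7.68 and 9.08 in cocaine arrays of D2 controls and mutants. The only other tested gene of those cells, the acetylcholine transporter Slc18a3, did not pass (0.37, SE 0.165, adjusted p = 0.155), but did with the glial covariate (0.84, adjusted p = 0.0267) and without D2 control cocaine replicate 1 (0.48, adjusted p = 0.0419) or D2 mutant cocaine replicate 1 (0.48, adjusted p = 0.0428). It was 0.21 without D2 control saline replicate 2 (adjusted p = 0.444). The largest rises were those of Afp (7.45, SE 0.142), Ccdc141 (6.10), Dach2 (5.78), Ndnf, a secreted neurotrophic factor (5.04, SE 0.117, adjusted p = 3.87e-21, 33.0-fold), Gbe1 (4.18), Corin (3.93) and Bank1 (3.50). They were followed by the prostaglandin dehydrogenase Hpgd (3.33), Acoxl (3.29), Serpinb1b (3.16), the complement regulator Cd55 (2.79) and Pkib (2.47). Of these 12 all but Bank1 and Serpinb1b lay under the floor in D2 controls, where background limits the fold.

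The largest falls in D2 mutants were those of Marveld3 (-1.47), Reep6 (-1.42), Trim25 (-1.38), Klc3 (-1.24), the semaphorin receptor Plxnd1 (-1.17), Epop (-1.06), the transcription factor Stat6 (-0.98), Cpne2 (-0.97), Apol8 (-0.97), the neurotrophic factor Nrtn (-0.96) and Rassf3 (-0.96). The call of Trim25 (adjusted p = 0.0434) ended without any 1 of 10 arrays, such as D2 control saline replicate 1 (-1.13, adjusted p = 0.146).

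Of the 9 D1 MSN markers 4 rose in D2 mutants and 5 did not pass (4 adjusted over the list alone, median 0.25, camera adjusted p = 0.00329, and 0.418 with an estimated correlation). That median was 0.119 with 2 rises under the glial covariate (adjusted p = 0.0236) and 0.557 with 5 rises under the most variable probe set (adjusted p = 0.000265). The fourth was Slc35d3 (0.56, SE 0.155, adjusted p = 0.0174), whose call ended without D2 control saline replicate 2 (0.47, adjusted p = 0.0626) or 3 (0.49, adjusted p = 0.0579). Tac1 (0.19), Ebf1 (0.25), Eya1 (0.06), Pdyn (-0.02) and Sfxn1 (-0.15) did not pass. Among 11 D2 MSN markers Drd2 and Cd4 (-0.29) fell, Upb1 (0.61, adjusted p = 1.17e-05) rose and 8 did not pass (1 rose and 2 fell adjusted over the list alone), with Penk at 0.00 and Gpr6 at -0.06. The wider subtype lists did not pass in D2 mutants. Of 100 D1-enriched genes 17 rose and 3 fell in cocaine and 8 rose and 3 fell in saline arrays, and of 100 D2-enriched genes 16 rose and 4 fell and 15 rose and 4 fell. D1-enriched medians were 0.07 in cocaine (adjusted p = 0.652) and 0.02 in saline arrays (adjusted p = 0.373), and D2-enriched medians were 0.08 (adjusted p = 0.652) and 0.06 (adjusted p = 0.214, but 0.0202 without D1 control cocaine replicate 3 and 0.046 without D2 control saline replicate 3). Other choices did pass, at the preset correlation; with an estimated one these 4 main values were at 0.995. With 200 genes per list these were the D2-enriched genes in cocaine arrays (0.172, adjusted p = 0.0277) and the D1-enriched in saline arrays (0.08, adjusted p = 0.0277), and without a filter the D2-enriched in saline arrays (0.061, adjusted p = 0.0216). With fixed marker lists the D1-enriched passed in cocaine (0.336, adjusted p = 0.000904) and saline arrays (0.197, adjusted p = 0.0331).

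Glial markers were higher in D2 mutants. Of 12 oligodendrocyte markers 8 rose and 4 did not pass (9 rose adjusted over the list alone, median 0.35, adjusted p = 4.89e-05, and 0.418 with an estimated correlation), including Ermn (1.75), Opalin (0.34) and Cnp (0.31). Of 9 astrocyte markers 2 rose, Ntsr2 (0.81) and Gja1 (0.62), and 7 did not pass (6 rose adjusted over the list alone, adjusted p = 0.00536, and 0.418 with an estimated correlation). The call of Gja1 ended without D2 control saline replicate 1 (0.58, adjusted p = 0.0557) or D2 mutant saline replicate 2 (0.55, adjusted p = 0.0626). With the glial marker mean as a covariate Drd1 (0.56, SE 0.165, adjusted p = 0.0648) and Slc35d3 (0.26, SE 0.221, adjusted p = 0.736) did not pass, and Isl1 (0.86, SE 0.181, adjusted p = 0.00503) and Zfp521 (0.99, SE 0.088, adjusted p = 2.47e-08) did. Of the D2 MSN markers Drd2 (-0.40, adjusted p = 0.272) and Cd4 (-0.29, adjusted p = 0.202) did not pass with it, and Upb1 (0.64, adjusted p = 0.00303) did.

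Beside those glial markers, 5 of 12 protocadherins rose in D2 mutants and 7 did not pass (6 adjusted over the list alone, adjusted p = 7.06e-05, and 0.418 with an estimated correlation), such as Pcdhb15 (1.28) and Pcdhb21 (0.95). Of 36 ribosomal protein genes 7 rose, among them Rpl7a (0.39) and Rps7 (0.25), and 29 did not pass (10 rose adjusted over the list alone, adjusted p = 0.000592, and 0.573 with an estimated correlation). Both named ribosomal calls ended with the glial covariate. Of 63 oxidative phosphorylation genes 1 rose (Cyc1 0.26), 2 fell (Ndufa7 -0.29, Cox8a -0.25) and 60 did not pass (adjusted over the list alone none passed). That list's adjusted p was 0.0436, 0.933 with an estimated correlation, 0.922 under cyclic loess and 0.122 under median centring, and each of its 3 gene calls ended without any 1 of several arrays, such as D2 control saline replicate 3 (Cyc1 0.25, Ndufa7 -0.24, Cox8a -0.24). Of 11 muscle genes 5 rose and 6 did not pass (5 adjusted over the list alone), namely Tnnt2 (1.61), Tnni1 (1.34), Tnnt1 (0.80), Acta1 (0.29) and Myh7 (0.37), the last named after its value was seen. Their list had an adjusted p of 0.0864, 0.418 with an estimated correlation and 0.037 under cyclic loess, and under median centring its median was -0.03.

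Of 24 imprinted genes 5 rose in D2 mutants, including Plagl1 (1.51) and Meg3 (0.55), and 19 did not pass (6 rose and 2 fell adjusted over the list alone). Of 23 H3K9 machinery genes Atf7ip rose (0.36), 3 fell, including the heterochromatin protein Cbx5 (-0.30) and the demethylase Kdm3b (-0.40), and 19 did not pass (3 rose and 4 fell adjusted over the list alone, adjusted p = 0.057). The target Ehmt2 was among those that fell. Kdm3b did not pass without D2 control saline replicate 1 (-0.38, adjusted p = 0.0537) or D2 mutant saline replicate 2 (-0.37, adjusted p = 0.0557), nor Atf7ip without any 1 of 11 arrays, such as D2 mutant saline replicate 3 (0.32, adjusted p = 0.115). Dach2 rose among 16 developmental transcription factors and 15 did not pass (median -0.06, mean 0.31, camera down). The tyrosine hydroxylase gene Th (1.46) rose among GABAergic interneuron markers, Nrn1 (1.44) among cortical markers (median -0.11, mean 0.18, camera down), Rgs5 (0.87) among endothelial and mural markers, and Nr4a3 (0.69) among immediate early genes. The call of Nr4a3 ended without D2 control saline replicate 1 (0.59, adjusted p = 0.0729), D2 mutant saline replicate 2 (0.62, adjusted p = 0.0596) or 3 (0.65, adjusted p = 0.055).

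Receptor and channel genes of D2 mutants moved both ways. Gabrb1 (1.57) rose while Gabra5 (-0.62) and Gabra3 (-0.55) fell among 9 GABA-A subunits (6 not passing, median -0.10, mean 0.02, camera down). Grm8 (-0.80) and Grm3 (-0.41) fell and Grik4 (0.28) rose among 18 glutamate receptors (1 rose and 4 fell adjusted over the list alone). Of 33 potassium channels 3 rose, including Kcna6 (1.64), 3 fell, including Kcnd1 (-0.38), and 27 did not pass (median 0.01, mean 0.03, camera down, and a median of -0.01 under cyclic loess). Scg2 (0.71) rose and Cartpt (-0.33) fell among 15 neuropeptides (median 0.00, mean 0.07, camera down). Fdps (0.33) rose and Lss (-0.34) fell among 17 cholesterol genes, and Asns (0.26) rose and Hspa1a (-0.31) fell among 29 heat shock genes. The calls of Gabra3 (-0.47, adjusted p = 0.122), Grik4 (0.22, adjusted p = 0.0848), Lss (-0.28, adjusted p = 0.0814) and Hspa1a (-0.29, adjusted p = 0.0676) ended without D2 mutant saline replicate 2, among other arrays. Those of Cartpt (-0.25, adjusted p = 0.148) ended without D2 control saline replicate 2 and of Fdps (0.29, adjusted p = 0.084) without D2 mutant saline replicate 3, again among others. The 18 pan-MSN markers did not pass.

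In D2 mutants 1011 genes rose and 459 fell, so that 68.8% of 1470 calls rose, and 51.4% under median centring. With the glial covariate 413 genes passed, of which 400 were among the 1470. The oligodendrocyte marker mean, part of that covariate, was 0.301 to 0.684 on D2 mutant arrays and -0.662 to 0.124 on D2 controls. The covariate thus overlaps with genotype and widens the errors, so the lost calls do not show a glial source. With the array whose source name disagrees counted as a control, although its Ehmt2 level lay in the mutant range, 855 genes passed.

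**Figure D3:**
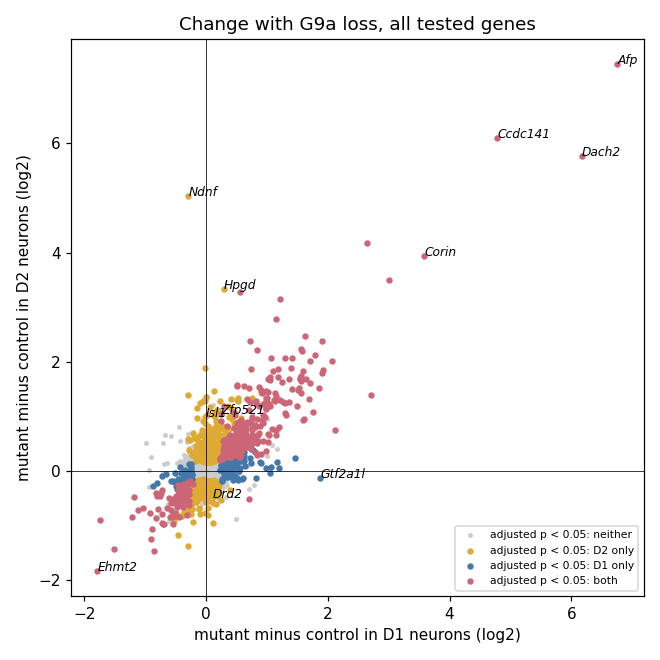
Log2 fold change of each of 12017 genes after G9a loss in D1 neurons (x axis) and in D2 neurons (y axis), 1 point per gene, coloured by whether it passed in neither, D2 only, D1 only or both. Afp and Dach2 lie far out on both axes (6.76 and 7.45, 6.17 and 5.78), and Ndnf far out on the D2 axis (5.04).

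The effects in the 2 subtypes shared genes. Of 373 genes that rose in D1 mutants 263 also rose in D2 mutants (70.5%), where 31.4 would be shared if the lists were independent, and of 134 that fell 89 also fell (5.12 for independent lists, Fisher's exact p = 2.32e-95). Across 12017 genes the effects had a Pearson r of 0.657, genes not being independent replicates. Of the D1 calls 93.5% had the same sign in D2, and of the D2 calls 79.3% had the same sign in D1. The 263 shared rises were a smaller part of the 1011 rises in D2 mutants, and the 89 shared falls of the 459 falls there.

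The difference between the subtypes was tested directly as the D2 effect minus the D1 effect. Ndnf differed most (5.33, adjusted p = 3.89e-17), followed by Hpgd (3.04), Acoxl (2.72), Serpinb1b (1.95), Anxa10 (1.90), the immune receptors Btla (1.66) and Cd2 (1.38), Cd55 (1.64), Gbe1 (1.54), the Polycomb-associated repressor Bcor (1.36), Gse1 (1.34) and Kazald1 (1.33). Ndnf, Hpgd, Acoxl, Anxa10, Btla and Cd2 lay under the floor of 6 in every group but the D2 mutants, so background limits the size and order of these differences. The effect was lower in D2 for Gtf2a1l (-2.01, adjusted p = 1.99e-10), Cst12 (-1.36), Zranb3 (-1.33), Crct1 (-1.23), the neuropeptide Y receptor Npy1r (-1.22), Rassf3 (-1.08), Ceacam10 (-0.99), Cd52 (-0.92), Pak6 (-0.79), Zfp775 (-0.77), Gpr149 (-0.74) and Krt73 (-0.73). Gtf2a1l, Cst12, Crct1, Cd52 and Krt73 lay under the floor in every group but those of D1 mutants, with the same limit. Among subtype markers the effect was higher in D2 for Isl1 (0.99, adjusted p = 0.00287), Zfp521 (0.79, adjusted p = 2.7e-06) and Upb1 (0.80, adjusted p = 0.000572), while Drd1 (0.48, adjusted p = 0.168), Slc35d3 (0.41, adjusted p = 0.485) and Drd2 (-0.60, adjusted p = 0.0779) did not pass. Without D1 control cocaine replicate 3 Drd2 passed (-0.65, adjusted p = 0.0324). Lhx8, named after its values were seen, differed (1.11, adjusted p = 0.0122), but not without D1 control saline replicate 1 (1.08, adjusted p = 0.0569). Gabrb1 (1.07), Plagl1 (0.80) and Asns (0.36) also differed, the last ending without any 1 of 16 arrays, such as D1 control saline replicate 1 (0.35, adjusted p = 0.133). Without that array the calls of Npy1r (-1.10, adjusted p = 0.0556), Pak6 (-0.73, adjusted p = 0.0638), Zfp775 (-0.70, adjusted p = 0.0685) and Gpr149 (-0.61, adjusted p = 0.132) ended too.

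As lists, 2 of 9 D1 MSN markers had a higher effect in D2 and 7 did not pass (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0538, and 0.904 with an estimated correlation), and 1 of 11 D2 MSN markers did (1 and 1 adjusted over the list alone, adjusted p = 0.61). The D1 MSN list passed without any 1 of 9 arrays, such as D1 control cocaine replicate 3 (adjusted p = 0.00644). The 12 oligodendrocyte markers did not pass singly over all genes (5 higher adjusted over the list alone, median 0.34, adjusted p = 0.000421, and 0.719 with an estimated correlation), nor did the 9 astrocyte markers (2 higher adjusted over the list alone, median 0.37, adjusted p = 0.00147, and 0.719 with an estimated correlation). Ribosomal (median 0.11, adjusted p = 0.0216) and oxidative phosphorylation genes (median 0.07, adjusted p = 0.0463) were called by camera but had adjusted p = 0.904 each with an estimated correlation, and 0.13 and 0.562 under cyclic loess. The 12 protocadherins did not pass (adjusted p = 0.066).

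In this contrast 79 genes were higher and 40 lower in D2 (66.4% of 119 higher, and 56.4% under cyclic loess). The count was 50 without D1 control saline replicate 1, 72 without D1 control saline replicate 2 and 71 without D2 mutant saline replicate 2. It was 56 with the glial covariate, and 18 with the disputed array as a control, where Isl1, Zfp521 and Upb1 did not pass.

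Cocaine was compared with saline in each subtype and genotype to ask what repeated cocaine changed 2 h after the last dose. In D1 controls the orphan nuclear receptor Nr4a3 (1.58, SE 0.31), Shisa2 (1.71, SE 0.269, adjusted p = 0.0158), the synaptic pentraxin Nptx2 (0.93, adjusted p = 0.0303), the insulin signalling adaptor Irs2 (0.89, adjusted p = 0.0392), Mnt (0.68, adjusted p = 0.0303), Snhg10 (0.69), Fam122a (0.53) and Gramd1b (0.47) rose. Nr4a3, Snhg10, Fam122a and Gramd1b passed by a hair, with adjusted p rounding to 0.05. In D1 mutants Nr4a3 (2.04, SE 0.274, adjusted p = 0.000383), Shisa2 (1.84), Midn (1.18), Apold1 (1.11, adjusted p = 0.000134), the immediate early genes Egr4 (2.15-fold) and Egr1 (0.75), the clock gene Per2 (0.90), Irs2 (0.79), Ccdc85b (0.61) and Slc41a1 (0.59) rose, and Slc23a3 (-0.51) fell. The 8 calls in D1 controls became 0 without D1 control cocaine replicate 1, 16 without cocaine replicate 2, 70 without cocaine replicate 3, 2 without cocaine replicate 4, and 0 without saline replicate 1 or 2. With the 3' to 5' covariate the D1 control count was 0, and it was 0 with only the groups compared, but far higher with array weights. The 11 calls in D1 mutants became 6 without D1 mutant saline replicate 1, 42 without saline replicate 2, 7 without saline replicate 3, 3 without cocaine replicate 2 and 7 without cocaine replicate 3.

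**Figure D4:**
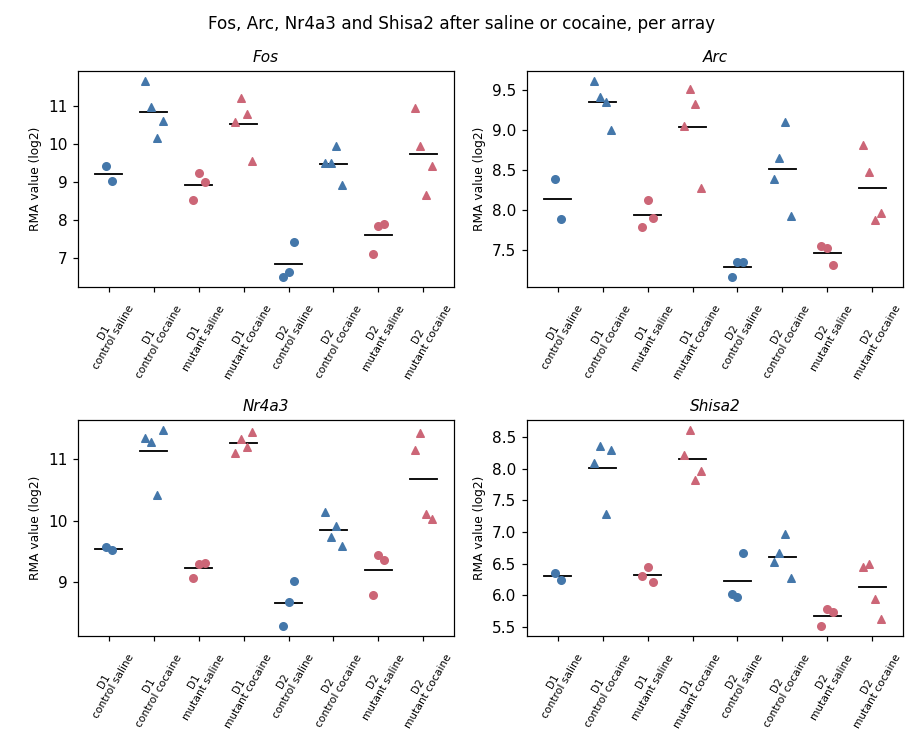
Log2 expression of Fos, Arc, Nr4a3 and Shisa2 on each array after saline (circles) or cocaine (triangles) by subtype and genotype, with controls in blue, mutants in red and the group mean as a line. Fos was 2.62 higher with cocaine in D2 controls, and Nr4a3 2.04 higher in D1 mutants.

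In D2 controls the immediate early genes Fos (2.62, adjusted p = 0.00504) and Arc (1.23, adjusted p = 0.0497) rose. The 14 that fell were led by the kinase scaffold Mapk8ip2 (-0.71), Tmcc2 (-0.68), St6galnac6 (-0.64), Rapgef1 (-0.64), Man2a2 (-0.58), Zmiz2 (-0.57), Atg9b (-0.57), Pigl (-0.54), Nhlrc3 (-0.51), B4galt2 (-0.49), Ubqln4 (-0.44) and Zfp521 (-0.42). In D2 mutants limma called 0 genes, with 588 at an unadjusted p under 0.05 where chance gives 601, and the smallest p-values belonged to Nr4a3 (1.48, adjusted p = 0.0799), Fos (2.14, adjusted p = 0.108), Acadl (1.02), Rnf217 (1.07) and Slitrk6 (-1.05). The 16 calls in D2 controls became 5 without D2 control cocaine replicate 1, 4 without cocaine replicate 3, 48 without cocaine replicate 4, and 2, 8 and 2 without saline replicates 1, 2 and 3. The 0 in D2 mutants became 5 without D2 mutant cocaine replicate 3, 3 without cocaine replicate 4 and 1 without saline replicate 2. Without the 3 arrays with high Ttr, D1 controls had 69 calls, D2 controls 9 and D2 mutants 2.

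Immediate early genes as a list pointed up after cocaine in each subtype and genotype. Of the 21, 1 rose in D1 controls (8 adjusted over the list alone, median 0.54, adjusted p = 4.65e-08, and 0.437 with an estimated correlation). In D1 mutants 3 rose (17 adjusted over the list alone, median 0.79, adjusted p = 2.66e-16, and 0.18 with an estimated correlation). In D2 controls 2 rose (4 adjusted over the list alone, median 0.27, adjusted p = 1.24e-12, and 0.196 with an estimated correlation). In D2 mutants 21 did not pass over all genes (10 rose adjusted over the list alone, median 0.59, adjusted p = 6.72e-15, and 0.193 with an estimated correlation).

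Ribosomal protein and oxidative phosphorylation genes also moved as lists with cocaine, without a member passing over all genes. In D1 controls the ribosomal median was 0.32 (22 rose adjusted over the list alone, adjusted p = 1.73e-11, and 0.437 with an estimated correlation) and the oxidative phosphorylation median 0.24 (25 adjusted over the list alone, adjusted p = 1.16e-14, and 0.437). The RNA quality measure of D1 controls was also higher with cocaine (2.167 to 2.904) than with saline (1.956 and 2.012). In D1 mutants the medians were 0.18 (adjusted p = 6.87e-05, and 0.577) and 0.15 (3 adjusted over the list alone, adjusted p = 5.48e-10, and 0.519), with 0.296 and 0.389 under cyclic loess. In D2 controls they were -0.14 (adjusted p = 0.00586, and 0.913 with an estimated correlation) and -0.10 (adjusted p = 0.0319, and 0.913), with 0.462 and 0.756 under cyclic loess. In D2 mutants they were 0.12 (adjusted p = 1.83e-06, and 0.598) and 0.06 (adjusted p = 0.000312, and 0.681). Camera also called pan-MSN markers (median 0.18, adjusted p = 0.000683, and 0.519 with an estimated correlation) and protocadherins (median -0.15, adjusted p = 0.00516, and 0.577) in D1 mutants, neither of them under cyclic loess (0.389 and 0.0635). It called oligodendrocyte markers (median -0.27, adjusted p = 0.046, and 0.913) and imprinted genes (median 0.06, adjusted p = 0.0137, and 0.196) in D2 controls, and imprinted genes in D2 mutants (median 0.10, adjusted p = 0.019, and 0.193).

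Pooled over the 4 strata, in a test added after the data were seen, cocaine raised 78 genes and lowered 18, led by Nr4a3 (1.57, SE 0.142, adjusted p = 5.63e-07), Fos (2.00, SE 0.217, adjusted p = 7.71e-06), Nr4a1 (1.21), Egr2 (1.14), Shisa2 (2.14-fold), Arc (1.08), Fosl2 (1.05), Tiparp (0.99), Rnd3 (0.92), Bcl6 (0.89), Junb (0.83) and Midn (0.81). Htr4, a serotonin receptor, fell (-0.38), as did Hpgd (-0.37) and Sesn1 (-0.27). Of 21 immediate early genes 13 rose in that pooled test (adjusted p = 3.16e-32, and 0.0113 with an estimated correlation). D1 arrays alone gave 90 calls and D2 arrays alone 16. The cocaine effect differed between subtypes for 3 genes, lower in D2 for Shisa2 (-1.35, adjusted p = 0.0444), Apold1 (-0.83, adjusted p = 0.0154) and St6galnac6 (-0.56, adjusted p = 0.0154).

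Whether G9a loss altered the cocaine effect was tested as the difference of the cocaine effects in mutants and controls. In D1 neurons limma called 0 genes (1340 at an unadjusted p under 0.05), with Inpp4a (1.02, adjusted p = 0.0837), Trim9 (-1.11), Calb2 (1.15), Ogdh (0.95) and Slc25a30 (1.18) nearest. In D2 neurons limma called 0 genes (583 at an unadjusted p under 0.05), with Mapk8ip2 (0.74, adjusted p = 0.561), Acadl (1.34), St6galnac6 (0.54), Zfp521 (0.49) and Rapgef1 (0.58) nearest. The D1 count was 5 under cyclic loess and higher still with array weights. It was 1 without D1 control cocaine replicate 1 and 7 without cocaine replicate 3, and the D2 count was 1 without D2 mutant saline replicate 2. Of the lists, camera called ribosomal (median 0.28, adjusted p = 7.31e-10) and oxidative phosphorylation genes (median 0.17, adjusted p = 1.55e-06) in D2, both at adjusted p = 0.891 with an estimated correlation, the second at 0.344 under cyclic loess. Oligodendrocyte markers (adjusted p = 0.0505, and 0.891 with an estimated correlation) passed there only under cyclic loess (0.0312) and median centring (0.0179), and D1 MSN markers (adjusted p = 0.0546, and 0.891) only under median centring (0.0295). Across genes the cocaine effects in mutants and controls had a Pearson r of -0.013 in D1 and 0.183 in D2.

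Of the lists with fewer than 5 tested members, which were not tested as lists, the tested numbers were 2 cholinergic interneuron, 3 oligodendrocyte precursor, 4 microglia, 0 blood, 4 ependymal and choroid plexus and 2 germline genes.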

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

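The tests of D1 neuron RNA, of the fold that Isl1 and Zfp521 keep with the glial covariate, of the position of rises within each subtype, and of microglia and vessel markers were chosen after the results were seen, as were Lhx8, the pooled cocaine contrasts and the genes beyond the target and markers that were examined for single arrays.

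Drd1, Isl1, Zfp521 and Slc35d3 rose in D2 mutants, and RNA of D1 neurons carried into these immunoprecipitates would raise all D1-enriched genes, but the other 135 implied a median share of 3.06% (95% bootstrap interval 0.123 to 7.61), below the 20.7% (17.6 to 24) that Zfp521 needs, which argues against it for that gene. Drd1 (8.99%, 5.06 to 13.6), Isl1 (8.89%, 6.17 to 12.1) and Slc35d3 (4.22%, 1.72 to 7.31) need shares whose intervals overlap the first, so it stays open for them. Tac1 implied as much (9.13%, 0.603 to 18.7) and Ebf1 3.03% (-0.815 to 7.86), both with wide intervals. Eya1 (0.0468%, -0.196 to 0.354), Pdyn (-0.106%, -1.96 to 2.16) and Sfxn1 (-1.78%, -3.41 to 0.0331) implied far less, Eya1 and Pdyn near the floor. The upper ends for Eya1 and Sfxn1 lie below the lower ends that Drd1, Isl1 and Slc35d3 need. That for Pdyn lies below those of Drd1 and Isl1. Single D1-enriched genes thus go both ways. At 4.22% 16 of the 20 most D1-enriched genes lay below their predicted rise (median -0.249, interval -0.426 to -0.092), against 10 of 20 above the floor (-0.359 to 0.216). At 8.89% 18 of the 20 most D1-enriched genes (-0.638 to -0.298) and 82 of the 135 (-0.207 to -0.021) lay below it. These intervals exclude 0 and go against that share, while that of the 20 above the floor (-0.592 to 0.059) reached 0. More glial RNA was to be read as the cause if fewer than 3 of the 4 genes passed with the glial covariate, and 2 did, so that criterion was met. It was afterwards read as undecided, since Drd1 kept its fold (0.54, SE 0.108, before and 0.56, SE 0.165, after) and lost its call to a wider error, while Slc35d3 shrank from 0.56 (SE 0.155) to 0.26 (SE 0.221) and Isl1 and Zfp521 passed with at least 87.3% of their folds. Of 100 splits of the D2 arrays, drawn from 1400 possible, 4, the real one included, gave a D1 marker median as large as 0.25 (highest other 0.32). That lies too near the 5% level for 100 draws to settle, and the list was 1 of 22 tested, so chance is not excluded for it. An effect of G9a loss on these genes stays open as a hypothesis, with glial RNA not excluded for Drd1 and Slc35d3, nor RNA of cholinergic interneurons for Isl1.

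Genes that rose at least 2-fold outnumbered those that fell in mutants, 75 to 7 in D1 and 117 to 7 in D2. Under cyclic loess and median centring the share of rises stayed at 89.9% or more. Both were applied on top of the deposited values, whose array medians were already close (5.70 to 5.82). They could hardly move calls of at least 2-fold, so the authors' normalization stays open as the cause. Strain differences beside the Cre transgene, which differs between the subtypes, or at another single locus are argued against by position as the main source, since at most 4% of the 2-fold rises in D1 (3 of 75), 3.42% in D2 (4 of 117) and 5.08% of those in both (3 of 59) lay within any 50 neighbouring tested genes. With the glial covariate 100% of the rises in D1 and 92.3% in D2 passed, which argues against glial RNA as their main source. A release of silenced genes by G9a loss is a candidate explanation that these tests leave open, as is an effect of Cre itself, which the design does not separate from genotype.

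Oligodendrocyte and astrocyte markers differed between the subtypes in their response to G9a loss (D2 minus D1 medians 0.34 and 0.37) by camera, but with no member passing over all genes and adjusted p = 0.719 each with an estimated correlation, and were higher in D2 mutants (0.418 each with an estimated correlation). RNA quality as the cause is argued against, since the oligodendrocyte median was 0.349 with the 3' minus 5' covariate and 0.35 without. A lower share of RNA from the tagged neurons would raise all other cell types alike, and the median of 10 microglia and vessel markers was -0.292 relative to oligodendrocyte markers with an interval of -0.645 to 0.05, so it could not be excluded. Of 100 splits, drawn from 1400 possible, 3, the real one included, gave an oligodendrocyte median as large (highest other 0.40). That too lies near the 5% level for 100 draws, and the list was 1 of 22 tested, so chance is not excluded. A change in oligodendrocytes or in what D2 neurons express stays untested.

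The difference between the subtypes in the effect of G9a loss called 119 genes. Of 100 splits of genotype within subtype and drug 2, the real one included, called as many. The highest other called 435, several times the real count. These splits break up the genotype effect within each subtype. They could therefore not test chance for the difference between subtypes alone, and chance is not excluded for these calls. Splits that exchange the labels unequally in D1 and D2 bring the genotype effect itself, which the subtypes share (Pearson r 0.657), into the contrast. By construction such splits can call more genes than the real one. Which splits did so was not examined. The effect was higher in D2 for Ndnf (5.33), Hpgd (3.04), Acoxl (2.72), Serpinb1b (1.95), Anxa10 (1.90), Btla (1.66), Cd55 (1.64), Gbe1 (1.54), Cd2 (1.38), Bcor (1.36), Gse1 (1.34), Kazald1 (1.33), Lhx8 (1.11), Isl1 (0.99), Zfp521 (0.79) and Upb1 (0.80). It was lower in D2 for Gtf2a1l (-2.01), Cst12 (-1.36), Zranb3 (-1.33), Crct1 (-1.23), Npy1r (-1.22), Rassf3 (-1.08), Ceacam10 (-0.99), Cd52 (-0.92), Pak6 (-0.79), Zfp775 (-0.77), Gpr149 (-0.74) and Krt73 (-0.73). The ribosomal protein (0.11) and oxidative phosphorylation (0.065) lists also differed between the subtypes by camera, though not with an estimated correlation.

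The cocaine effect differed between genotypes in D2 neurons for the ribosomal protein (0.28) and oxidative phosphorylation (0.17) lists by camera, and not with an estimated correlation. It differed between subtypes, D2 minus D1 over both genotypes, for Shisa2 (-1.35), Apold1 (-0.83) and St6galnac6 (-0.56), and by camera for the ribosomal protein (-0.22) and oxidative phosphorylation (-0.21) lists (adjusted p = 5.44e-08 and 3.21e-13, and 0.927 each with an estimated correlation).

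Single arrays stood apart from their group in 11 of 144 values examined in the 4 groups of 4 arrays, where chance flags about 1 in 20 groups, or 7.2. The number given is the gap to the nearest other array as a share of the group's range. In D1 control cocaine these were Isl1 in replicate 3 (0.869; 10.04 against 10.76 to 10.87 in the others) and Cd4 in replicate 4 (0.886). In D1 mutant cocaine they were Sfxn1 in replicate 3 (0.835) and Gucy1a1 in replicate 2 (0.979). In D2 control cocaine replicate 3 stood apart in Ttr (0.86; 11.40 against 5.40 to 6.24), Slc35d3 (0.846) and Gucy1a1 (0.872), and replicate 4 in Ndnf (0.841). In D2 mutant cocaine replicate 1 stood apart in the microglia marker mean (0.853), Gucy1a1 (0.839) and Cd4 (0.844).

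Of 1854 tested probe sets with no gene listed, which the gene counts leave out, 314 differed between D1 and D2 controls, 48 between mutants and controls in D1, 133 in D2, and 3 in the difference of these effects.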

How the results depend on the processing

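The fit without the 3 high-Ttr arrays, the list counts under other settings and the RNA quality alternatives were chosen after the data were seen. Signal near the array background limits the folds of genes such as Afp that are off in controls, and differences such as that of Ndnf, and groups of 2 to 4 arrays limit the cocaine contrasts. Where leaving out an array left D1 control saline with 1 array, it was assumed to vary like the other groups. The replicate numbers do not pair the arrays: deviations of arrays with the same number had a mean correlation of 0.018 and others -0.007, and 8 of 27 arrays correlated best with their own number. Results that are not called and change sign without being called were counted as the same. Of the named genes, 4676 values without 1 array stayed on their side of the threshold, called or not, 277 lost their call and 15 gained one. Under cyclic loess 308 stayed and 26 lost it, under median centring 327 and 13, with array weights 326 and 0 (14 gained), with the glial covariate 280 and 59, and 1 reversed (Gja1 in D2 mutants, -0.055). Gja1 is itself averaged into that covariate, which takes out part of its change by construction. The cause was not tested except where the construction of a setting gives it, as for a stricter fold or fewer arrays.

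Where counts of genes or lists moved by over 1.5 times or list calls changed, the values were these. With every probe set tested, cocaine called 6 genes in D1 mutants and 7 in D2 controls. With the most variable probe set the D1 MSN marker median in D2 minus D1 was 0.41 (passing). Without a filter that median was 0.159 (passing), D2-enriched genes in D2 mutant saline arrays were at 0.061 (passing), cocaine called 4 in D1 controls and 9 in D2 controls, and lists called were 9 in D2 minus D1 and 2 for cocaine by genotype in D1. With the filter at 7, cocaine called 20 in D1 controls. Under cyclic loess cocaine called 2 in D1 controls, 6 in D1 mutants and 5 by genotype in D1, with 2 lists in D2 minus D1, 1 for cocaine in D1 mutants and 3 in D2 controls. Under median centring cocaine called 2 in D1 controls and 1 in D2 mutants. With trend and robust moderation it called 14 in D1 controls. With only the groups compared it called 0 in D1 controls, 22 in D1 mutants and 1 in D2 controls.

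Array weights gave 969 for G9a loss in D1, 2293 in D2 and 352 for D2 minus D1, and for cocaine 461 in D1 controls, 218 in D1 mutants, 124 in D2 controls, 10 in D2 mutants and 54 by genotype in D1, with D1 MSN markers in D2 minus D1 at 0.142 (passing). With the replicate block cocaine called 4 in D1 controls, 31 in D1 mutants and 3 in D2 mutants, D1 MSN markers in D1 mutants were at 0.205 (passing), and lists were 5 for cocaine in D1 controls and 4 by genotype in D2. With the 3' to 5' covariate cocaine called 0 in D1 controls and 60 in D2 controls, with 2 lists in D2 controls and 1 by genotype in D1. With the glial covariate G9a loss called 413 in D2 and 56 in D2 minus D1, cocaine 7 in D1 mutants and 5 in D2 controls, with 2 lists in D2, 0 in D2 minus D1, 2 for cocaine in D2 controls and 1 by genotype in D1. With a fold of at least 1.5 there were 670 for D1 against D2, 199 for G9a loss in D1, 317 in D2, 76 in D2 minus D1 and 6 for cocaine in D2 controls. With an estimated correlation, lists called were 2 for D1 against D2, 1 for G9a loss in D1 and 0 in the other 8 contrasts set beforehand, where D1 MSN markers in D2 mutants (0.253) and D1-enriched genes in D1 mutant saline arrays (0.267) no longer passed. With the disputed array as a control G9a loss called 855 in D2, 18 in D2 minus D1, and cocaine 1 in D2 mutants. Without the 3 high-Ttr arrays cocaine called 69 in D1 controls, 9 in D2 controls and 2 in D2 mutants, D1 MSN markers in D2 minus D1 were at 0.16 (passing), and 5 lists were called by genotype in D2. With 50 genes per list D1-enriched genes in D1 mutant saline arrays were at 0.251 (not passing). With 200, D2-enriched genes in D2 mutant cocaine arrays were at 0.172 and D1-enriched genes in D2 mutant saline arrays at 0.08 (both passing). With fixed marker lists, D1-enriched genes were at 0.232 in D1 mutant cocaine arrays, 0.336 in D2 mutant cocaine and 0.197 in D2 mutant saline arrays (passing), and 0.059 in D1 mutant saline arrays (not passing).

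Leaving out each array in turn gave these ranges. Genes called were 2310 to 4083 for D1 against D2, 319 to 549 for G9a loss in D1, 1114 to 1675 in D2 and 50 to 139 for D2 minus D1. For cocaine they were 0 to 70 in D1 controls, 3 to 42 in D1 mutants, 2 to 48 in D2 controls, 0 to 5 in D2 mutants, 0 to 7 by genotype in D1 and 0 to 1 in D2. Lists called were 7 to 11 for D1 against D2, 1 to 3 for G9a loss in D1, 5 to 8 in D2 and 2 to 7 for D2 minus D1, and for cocaine 3 to 5 in D1 controls, 4 to 6 in D1 mutants, 3 to 5 in D2 controls, 3 to 6 in D2 mutants, 0 to 3 by genotype in D1 and 2 to 4 in D2. D1 MSN marker medians were 0.021 to 0.2 in D1, 0.196 to 0.323 in D2 (always passing) and 0.1 to 0.219 for D2 minus D1, and D2 MSN medians -0.077 to 0.077, -0.113 to -0.004 and -0.207 to -0.069. D1-enriched genes ranged from -0.038 to 0.07 (cocaine) and 0.075 to 0.297 (saline) in D1 mutants and from -0.008 to 0.141 and -0.025 to 0.114 in D2 mutants. D2-enriched genes ranged from -0.061 to 0.033 and -0.045 to 0.097 in D1 mutants and from 0.032 to 0.144 and 0.018 to 0.105 in D2 mutants. RNA quality differences by genotype were -0.048 to 0.141 in D1 and -0.026 to 0.072 in D2, and by drug 0.032 to 0.225 and -0.13 to -0.034, none passing in the exact permutation test.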

Other observations

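The tests of neighbouring genes, of Ehmt1 and of cholinergic interneuron genes, and the pooled cocaine contrasts, were chosen after the results were seen.

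Within D2 arrays of both genotypes, cocaine raised Fos (2.38), Nr4a3 (1.34), Arc (1.02), Irs2 (0.59) and the calmodulin kinase Camk1g (0.59) among 10 rises and 6 falls. Within D1 arrays it gave 80 rises and 10 falls. Of 21 immediate early genes 10 rose in D1 (adjusted p = 0.0854 with an estimated correlation) and 3 in D2 (adjusted p = 0.0374 with an estimated correlation). Over all strata the ribosomal (adjusted p = 1.51e-10, and 0.278 with an estimated correlation) and oxidative phosphorylation lists (adjusted p = 1.38e-15, and 0.278) were called by camera, and 1 imprinted gene rose (list adjusted p = 0.000501, and 0.0276 with an estimated correlation). The ribosomal and oxidative phosphorylation lists were called within D1 arrays (ribosomal median 0.214, adjusted p = 3.11e-15, and 0.148 with an estimated correlation; oxidative phosphorylation 0.189, adjusted p = 5.58e-24, and 0.128) and not within D2 arrays (-0.011, adjusted p = 0.62, and -0.026, adjusted p = 0.621). Their D2 minus D1 medians were -0.22 (adjusted p = 5.44e-08) and -0.21 (adjusted p = 3.21e-13), both at 0.927 with an estimated correlation. The pooled immediate early median was 0.63, and 1 of 100 splits, the real one, reached it (highest other 0.45). Taken alone this lies under the 5% level, and it is the least that 100 splits can give. The list was 1 of 22 tested and the contrast was added after the data were seen. The 100 draws therefore do not exclude chance once all lists are counted.

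Other splits of the arrays gave these counts. For D1 against D2 in controls 1 of 100 splits, the real one, called 3480 genes (highest other 1016), for G9a loss in D1 1 of 100 called 507 (highest other 167) and in D2 1 of 100 called 1470 (highest other 811), so chance is excluded at the 5% level for these. For cocaine in D1 mutants 1 of 35 splits, the real one, called 11 (highest other 3). Taken alone this lies under the 5% level, but it is the least that 35 splits can give. Other cocaine contrasts were split too, and the real count was 3 without D1 mutant cocaine replicate 2. Chance is therefore not firmly excluded for cocaine in D1 mutants. In D2 controls 3 of 35 called at least 16 (highest other 28), and chance is not excluded. In D2 mutants 35 of 35 splits called at least the real 0 (highest other 3), and for the cocaine difference between genotypes in D2 100 of 100 did (highest other 2). With a real count of 0 that outcome is fixed and decides nothing. Cocaine in D1 controls and its difference between genotypes in D1 were not split, since 1 of their groups has 2 arrays.

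Genes that rose in mutants lay next to each other on the chromosomes more often than random sets of the same mean level. Without pairs of 1 gene family, 24 neighbouring tested pairs both rose in D1 mutants, against 5 to 18 in 95% of 10000 random sets (permutation p = 3e-04), and 137 in D2 mutants, against 66 to 98 (permutation p = 1e-04, the smallest that these sets can give). Runs in D2 mutants included Isl1 with Emb and Mrps30, Sf3b5 with Plagl1 and Ltv1, Mal with Mtln and Acoxl, and the longer Hint3, Ncoa7, Hddc2, Tpd52l1, Rnf217 and Nkain2. Changes in expression that spread over neighbouring genes may account for part of the rises, as a hypothesis found and tested on the same arrays. Shared regulation of neighbours by other means was not tested.

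Ehmt1, the partner of G9a, differed between arrays of 1 group with a within-group SD of 0.35, higher than 96.7% of genes. A variant near Ehmt1 that segregates in the mixed strain background could cause this. Of the 20 genes whose deviations follow Ehmt1 most closely, 1 (Plxdc2) lay within 50 tested genes of it, where 0.17 would by chance, which does not decide it.

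In D2 mutants Lhx8 (1.17, SE 0.155) and Isl1 (0.98, SE 0.121) rose. More RNA of cholinergic interneurons in the D2 mutant immunoprecipitates could raise both, as a hypothesis. Of the 2 tested markers of these cells, Lhx8 cannot test this hypothesis, since its rise prompted it. The other, Slc18a3 (0.37, SE 0.165, adjusted p = 0.155), did not pass, which does not decide it. Slc18a3 passed without either of 2 arrays (0.483, adjusted p = 0.0419, without D2 control cocaine replicate 1, and 0.478, adjusted p = 0.0428, without D2 mutant cocaine replicate 1), and was 0.207 without D2 control saline replicate 2 (adjusted p = 0.444).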
